A study of Mus musculus with 6 samples.

How the data were processed

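Chromatin accessibility was measured by ATAC-seq, which reads out DNA open to a transposase, in nuclei from the ventral tegmental area of mice. Per the design text of the series, both genotypes received a viral vector for Cre recombinase, named for tyrosine hydroxylase (Th) and read here as driven by its promoter. A second, Cre-dependent vector encoded a nuclear green fluorescent protein, and fluorescent nuclei were sorted. Per the labels' protocols, libraries were made with a general DNA library kit, and no transposition step is described. Mice of the floxed Ogt genotype formed the knockdown group and mice without the floxed allele the control group, with 3 libraries each. Groups were taken from the genotype label. Knockdown replicate 1 has the floxed genotype in that label, while its title names the control genotype, so a grouping by title was run as an alternative. The labels do not say whether each library came from a separate animal. The p-values therefore measure only the spread between these libraries, which may be technical.

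The submitters' processing notes name FastQC, Trimmomatic, BWA, SAMtools 1.9, Picard, MACS2 and the mouse build mm10, without their roles. The counting program, any shift of reads for transposase binding and the rule that made the regions are not given in the sources used here. The libraries share 193148 regions, of which 94.6% are 401 bp wide and the widest is 1611 bp. Per the file headers, each region has a read count, an RPKM value and a score. The deposited counts are whole numbers without normalization and were used as they stand. The deposited RPKM values equal the count divided by region width and by 1 total per library, which gave the library totals. The deposited score equals the count times the mean library total over the library's own total, and was not tested. The written design had assumed peak lists per library. Because the tables hold counts on common regions, the count test given there as the fallback became the main test, and presence or absence of peaks was not analysed.

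Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group as the only term, TMM scaling and the package's filter on low counts. Regions with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower in knockdown, and 191693 regions passed the filter. Fold changes are log2 of knockdown over control. Levels are CPM of reads in regions with TMM scaling, given as mean ± SD of 3 libraries. A level of 3 reads equals 0.117 to 0.237 CPM depending on the library, so low levels rest on few reads. This floor covers counting error only; intervals of medians come from resampling genes and show the spread between genes.

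Regions were assigned to the nearest of 21887 protein-coding genes of the RefSeq table for GRCm38.p6, the assembly called mm10. The table gave gene bounds without strand or exons. A region within 1000 bp of either bound is called a gene-end region; others are within a gene or between genes. Start sites, exons, introns and UTRs were not told apart, and the nearest gene need not be the gene a region acts on. No genome sequence was used here, so motifs, GC content and repeats were not analysed.

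The rule for named genes was fixed before the data were examined, as were the gene lists. It takes 10 genes (Ogt, Oga, Stat3, Th, Slc6a3, Slc18a2, Drd2, Nr4a2, Pitx3 and Socs3) with their most accessible region within 5000 bp, the 10 called regions of largest fold change in each direction, and called members of 20 gene lists. List members quoted are among the 2 with the largest fold change per list and direction, a choice made later. Further regions of Ogt, Oga, Stat3, Th, Gfap and Aqp4 and the p53 target genes were singled out after their values were seen. Single regions of a few list genes are not reported here; they remain in the list counts and tests. The lists hold 396 entries, 395 matched by symbol and 1 by synonym. Regions of a list, up to 100000 bp from its genes, were set against all other assigned regions by Fisher's exact test, two-sided, with adjustment over 40 tests. Single regions described as near a list gene lie within the same distance. Regions of a gene are not independent, so these p-values describe regions and not animals. Exact two-sided permutation tests of 3 against 3 libraries cannot go below p = 0.1.

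Alternatives fixed at the same time were DESeq2 1.42.0 with a Wald test, no filter on low counts, each library left out in turn, grouping by title, list assignment within 10000 bp and gene ends of 3000 bp. Chosen after seeing the data were scaling by library totals, by reads in regions and by loess curves, and knockdown replicate 2 alone against the controls. A Mantel-Haenszel test over location and accessibility classes, camera of limma 3.58.1 with a preset correlation of 0.01 or an estimated one, a list of p53 target genes and 20 gene families were also chosen then. The fit with knockdown replicate 2 alone has 1 library in a group, so a call lost there need not mean a smaller change.

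The count test was tested on simulated data for knockdown against control, with 200 changed regions among 193148. It recovered 13.4% of 1.5-fold, 47.8% of 2-fold and 95.5% of 4-fold changes, with 3 false calls among 107. A first criterion, that most changes be recovered in each fold class of 2-fold or more, was not met in the 2-fold class. It was replaced after that result by a criterion on 4-fold changes, false calls and bias, so small changes may be missed. The simulation gave all regions the same spread (dispersion 0.02) and changed few of them, while 28.1% were called in the data. Its recovery shares therefore need not hold for these data.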

Results

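The study asked how lowering Ogt changes accessible chromatin in dopaminergic neurons of the ventral tegmental area, a midbrain region of reward processing. Ogt encodes the enzyme that attaches O-GlcNAc sugars to nuclear and cytoplasmic proteins. Sorted nuclei of 3 control and 3 knockdown libraries were compared. Library totals were 34384319, 66853563 and 52895584 reads for control replicates 1 to 3 and 42606274, 41025728 and 42678585 reads for knockdown replicates 1 to 3. Reads in regions numbered 13120042, 24440507 and 19876169 in control and 14067854, 12698758 and 15795872 in knockdown. These were 37.4% ± 0.809 (SD, n = 3) of reads in control and 33.7% ± 3.08 (SD, n = 3) in knockdown. The difference did not pass an exact two-sided permutation test (p = 0.2, smallest possible 0.1). No pair of libraries agreed within sampling noise.

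Ogt itself stayed accessible in each library. Of 8 regions within 5000 bp of Ogt, 4 rose and 2 fell in knockdown; both losses and 2 of the gains no longer passed with knockdown replicate 2 alone. The loss at 101636278 was also not called in DESeq2 (adjusted p = 0.077), nor the gain at 101681704 without knockdown replicate 3 (edgeR adjusted p = 0.054). The most accessible one, at a gene end (mm10 chromosome X, 101639785 to 101640185), had 11.1, 11.1 and 9.08 CPM in control replicates 1 to 3. Knockdown replicates 1 to 3 had 17.9, 14.96 and 14.7 CPM there, a log2 fold change of 0.61 (SE 0.14, edgeR adjusted p = 0.0033). A region inside the gene (101651080 to 101651822) rose from 1.57 ± 0.239 to 4.36 ± 0.941 CPM (SD, n = 3). Another (101656647 to 101657047) fell from 1.47 ± 0.0861 to 0.805 ± 0.0968 CPM (SD, n = 3; edgeR adjusted p = 0.045), a call lost in DESeq2 (adjusted p = 0.19) and without any single library (edgeR adjusted p = 0.066 to 0.13). The floxed exons are not given in the sources used here, so these regions do not check the genotype labels. The gene-end region no longer passed with library totals (log2 fold change 0.34, edgeR adjusted p = 0.081) or with knockdown replicate 2 alone (0.51, edgeR adjusted p = 0.056).

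**Figure D1:**
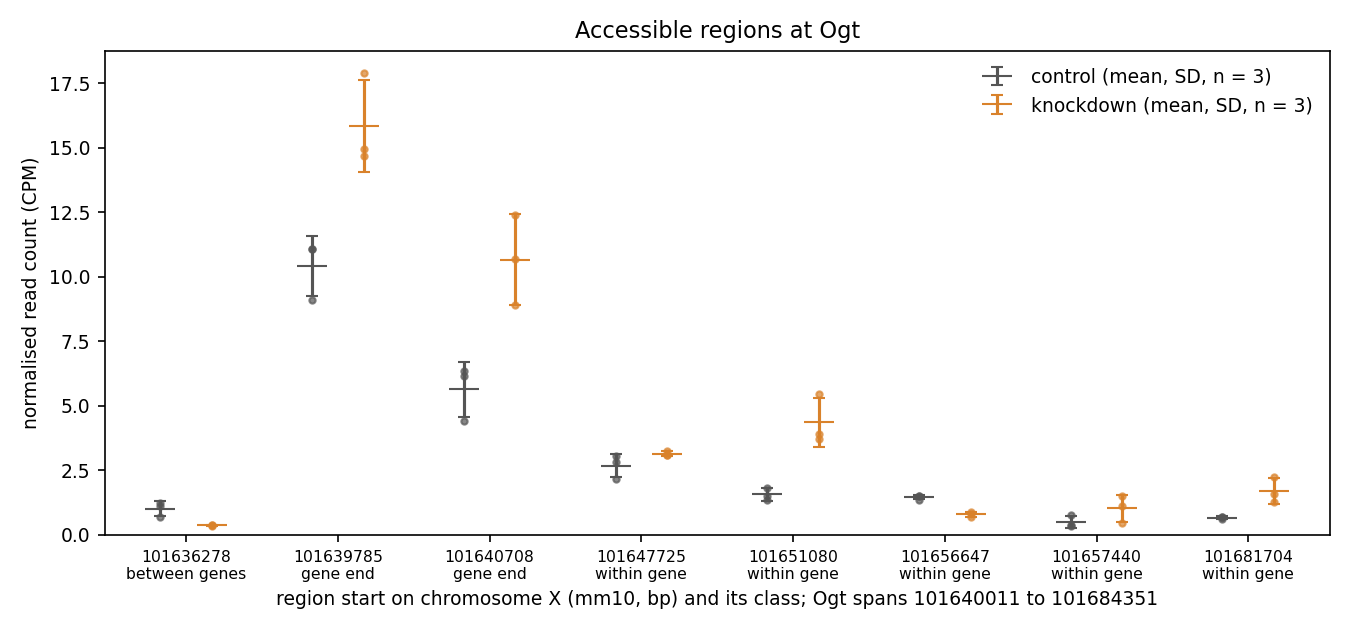
Normalised read count (CPM, vertical axis) of the 8 regions at Ogt, ordered by start on chromosome X (horizontal axis). Points are libraries and bars the mean and SD of 3; at the region starting at 101639785 the knockdown libraries lie at 14.7 CPM or more and the control libraries at 11.1 CPM or less.

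Knockdown nuclei differed from control nuclei at many accessible regions, and at gene ends more regions were called higher than lower with TMM scaling, but not with library totals (8.72% against 15.5%). Accessibility rose at 29459 and fell at 24360 of 191693 regions, 28.1% of those tested, and by 2-fold or more at 12739 and 9856. Among gene-end regions 32.7% rose and 6.94% fell. Within genes 11.8% rose and 13.5% fell, and between genes 15.3% and 13.5%. In the most accessible decile 39.5% rose and 4.64% fell, while in decile 8 the shares were 14.2% and 20.1%. Libraries correlated across regions at 0.940 to 0.975 within groups and 0.865 to 0.917 between groups. Knockdown replicate 1, whose title and genotype label disagree, correlated at 0.940 and 0.955 with the other knockdown libraries and at 0.865 to 0.888 with control.

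The split into gains and losses moved with the scaling. With TMM 54.7% of called regions were higher, with reads in regions 40.3%, and with library totals 21.7% (13072 higher, 47194 lower). The median log2 fold change of all regions was -0.0081, -0.12 and -0.27 in these scalings. The gene-end median was 0.22, 0.11 and -0.045, above the -0.053, -0.16 and -0.31 of the other regions, and under loess curves it was 0.049 against -0.024. Grouping by title gave 0 regions with edgeR at the adjusted threshold and 23390 at an unadjusted p under 0.05. Without control replicate 2, 19120 regions were higher and 14668 lower, and without control replicate 1, 15264 were lower.

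**Figure D2:**
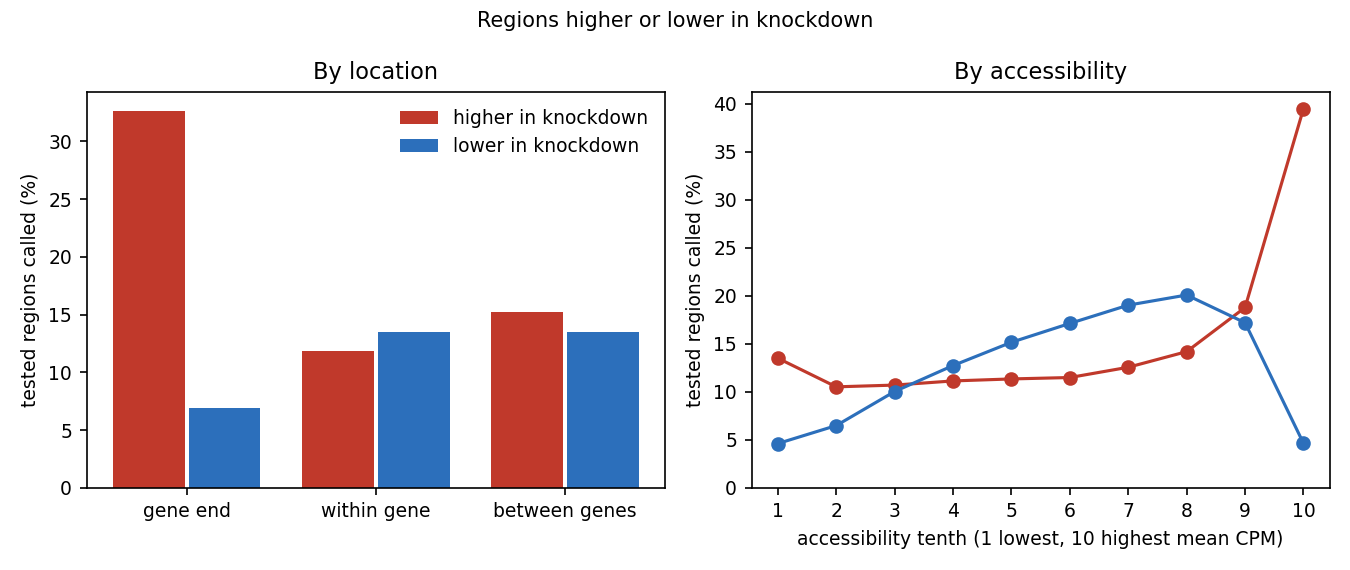
Percentage of tested regions called higher (red) or lower (blue) in knockdown (vertical axes) by location and by decile of mean accessibility (horizontal axes), from edgeR with TMM scaling and 3 libraries per group. Gene-end regions were higher in 32.7% and lower in 6.94%, which turned to 8.72% and 15.5% with library totals; in the most accessible decile 39.5% were higher.

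The largest gains included regions in or near zinc finger genes. A region inside Zfp37 (chromosome 4, 62200155 to 62200555) rose from 0.182 ± 0.0477 to 4.36 ± 0.520 CPM (SD, n = 3). One inside Zfp958 (chromosome 8, 4627293 to 4627693) rose from 0.143 to 3.51 CPM, and one 9327 bp from Zfp280d (chromosome 9, 72264891 to 72265291) from 0.199 to 4.53 CPM. A region 1047 bp from Rlf, also a zinc finger gene (chromosome 4, 121216168 to 121216568), rose from 0.627 ± 0.135 to 11.3 ± 0.408 CPM (SD, n = 3; log2 fold change 4.12, SE 0.22, edgeR adjusted p = 8.3e-09). The others lay nearest to Gm6614, Tgfa, encoding a ligand of the EGF receptor, Lrfn2, encoding a synaptic adhesion protein, Hdgfl1, Rfpl4b and Gm9733, at log2 fold changes of 4.03 to 4.52. Those of Lrfn2, Gm9733 and Rfpl4b lay 140380, 182520 and 579817 bp from the gene, beyond the 100000 bp used for lists. The Gm9733 region had 9.96, 1.27 and 1.13 CPM in knockdown replicates 1 to 3. Most of these regions lay near the level of 3 reads in control, so their folds are imprecise.

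The largest losses included a region inside Cacna2d4, encoding an auxiliary calcium channel subunit (chromosome 6, 119341394 to 119341794). It fell from 13.6 ± 0.345 to 1.76 ± 0.372 CPM (SD, n = 3; log2 fold change -2.94, SE 0.19, edgeR adjusted p = 3.1e-08). A region inside Cavin1, a caveolar coat gene (chromosome 11, 100960611 to 100961011), fell from 8.27 ± 1.22 to 1.00 ± 0.0534 CPM. One at an end of Dhdh (chromosome 7, 45481361 to 45481761) fell from 7.13 ± 0.882 to 0.945 ± 0.139 CPM. A region 141118 bp from Grin2b, encoding an NMDA receptor subunit, fell from 2.61 to 0.332 CPM. The rest lay nearest to Gm9595, Lnpk, Cadm1, an adhesion gene, Rnf165, Tspan17 and Lsm5, at log2 fold changes of -3.65 to -2.94. Those of Lnpk and Cadm1 lay 222992 and 202202 bp from the gene.

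Genes of dopaminergic identity gave mixed results. Drd2, the D2 dopamine receptor, rose at its most accessible region (chromosome 9, 49340185 to 49340585) from 10.1 ± 2.51 to 16.9 ± 0.909 CPM (SD, n = 3; log2 fold change 0.72, edgeR adjusted p = 0.0024). Pitx3, a transcription factor of midbrain dopaminergic neurons (chromosome 19, 46135992 to 46136392), rose from 16.4 ± 1.02 to 22.5 ± 2.71 CPM (SD, n = 3; log2 fold change 0.46, edgeR adjusted p = 0.0076). These were the only called regions of Drd2, among 12 within 5000 bp, and of Pitx3, among 3. The main regions of the dopamine transporter gene Slc6a3, the vesicular monoamine transporter gene Slc18a2 and the transcription factor gene Nr4a2 did not pass, at log2 fold changes of 0.16, 0.18 and -0.098. Th, encoding the rate-limiting enzyme of dopamine synthesis, had 267 ± 102 CPM in control and 197 ± 35.2 CPM in knockdown at its gene end (chromosome 7, 142899971 to 142900371), with an edgeR adjusted p of 0.074. Regions 1121 and 1725 bp beyond Th fell, at log2 fold changes of -0.77 and -0.62. These Th values rest largely on control replicate 2, which had 379 CPM at the gene end against 178 and 245 CPM in control replicates 1 and 3. Without it the gene-end value was -0.10 (edgeR adjusted p = 0.66) and the regions beyond had -0.40 and -0.19 (0.10 and 0.46). Both calls beyond the gene end were also lost in DESeq2 (adjusted p = 0.16 and 0.33) and without knockdown replicate 3 (edgeR adjusted p = 0.062 and 0.16), and the farther one without control replicate 3 (0.079) and with knockdown replicate 2 alone (0.052). The Th gene-end region passed without control replicate 1 (-0.66, edgeR adjusted p = 0.0079), without knockdown replicate 1 (-0.61, 0.016) and under the other scalings (-0.56 to -1.01). With library totals Pitx3 and Drd2 no longer passed (edgeR adjusted p = 0.29 and 0.051), nor did Pitx3 with loess curves (0.052) or knockdown replicate 2 alone (0.19).

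The dopaminergic identity list, 271 regions of 20 genes, had 45 regions higher and 17 lower, and 38 and 13 when adjusted over the list alone. Its lower regions were fewer than elsewhere (6.27% against 13.1%, Fisher's exact adjusted p = 0.0014), and its higher regions did not differ from the rest (adjusted p = 0.69). Camera gave this list an adjusted p = 0.87 with an estimated correlation. With library totals 20 of its regions were higher and 40 lower (median log2 fold change -0.20 against 0.060 with TMM). Its lower regions stayed scarcer than elsewhere there (odds ratio 0.51, Fisher's exact adjusted p = 1.5e-04). A region near Otx2, a midbrain transcription factor, rose from 0.357 to 2.66 CPM, and one within Aldh1a1, a retinaldehyde dehydrogenase gene, from 0.239 to 1.58 CPM. Regions nearest to Foxa2 and Lmx1a, regulators of the development of these neurons, fell from 2.75 to 0.563 CPM and from 3.65 to 0.972 CPM. The shortage of lower regions did not pass without control replicate 1, without knockdown replicate 2 or with that library alone (Fisher's exact adjusted p = 0.095, 0.081 and 0.051).

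Regions of STAT3 target genes, a pathway that the study's title names, were called higher more often than other regions. Stat3, the transcription factor itself, rose at a gene end (chromosome 11, 100939359 to 100939759) from 47.5 ± 3.88 to 65.2 ± 5.70 CPM (SD, n = 3; log2 fold change 0.46, edgeR adjusted p = 0.0024), and 1 region inside the gene fell (-0.49). The latter call was lost in DESeq2 (adjusted p = 0.054) and without control replicate 1 or 2 or knockdown replicate 1 or 3 (edgeR adjusted p = 0.13, 0.12, 0.058 and 0.060), and with knockdown replicate 2 alone (0.22). Socs3, a feedback inhibitor of cytokine signalling, rose at 3 of 4 regions, the most accessible (chromosome 11, 117963368 to 117963768) from 31.5 ± 2.26 to 48.9 ± 7.87 CPM (SD, n = 3). Among 225 regions of the STAT3 target list 77 rose and 12 fell, and 82 and 14 when adjusted over the list alone. The higher share was 34.2% against 15.2% of all assigned regions (odds ratio 2.92, Fisher's exact adjusted p = 2.4e-11). Camera gave an adjusted p = 0.39 with an estimated correlation. Examples were Gfap, the astrocyte intermediate filament (0.803 ± 0.184 to 8.84 ± 5.27 CPM), and Bcl2l1, an anti-apoptotic gene (2.28 ± 0.133 to 15.04 ± 2.98 CPM), while regions near Cebpd and within Bcl6 fell (-1.42 and -1.22). Without the 1 gene shared with the astrocyte list, 73 of 220 regions rose. Knockdown replicate 2 was the lowest knockdown library at 72.7% of the 77 higher regions of the STAT3 target list, against 50.4% of other higher regions (Fisher's exact p = 8.5e-05). For the astrocyte list this share was 85.4%. With knockdown replicate 2 alone the list had an odds ratio of 1.68 and a median log2 fold change of 0.17, against 2.92 and 0.25 with all libraries. The calls at the gene-end Stat3 region and the 3 Socs3 regions were lost there, though a fit with 1 knockdown library calls fewer regions. Without knockdown replicate 1 or 3 the list's odds ratios were 3.01 and 2.74. With library totals 41 regions of the list were higher and 27 lower, its median log2 fold change moved from 0.25 to -0.0074, and the Stat3 region had an edgeR adjusted p of 0.21, or 0.16 with loess curves. The list's higher regions stayed enriched with library totals (odds ratio 3.19, Fisher's exact adjusted p = 2.6e-08).

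The JAK-STAT list, of cytokine signalling genes, had 54 of 261 regions higher and 33 lower, and 59 and 40 when adjusted over the list alone (odds ratio for higher regions 1.46, Fisher's exact adjusted p = 0.037). Camera gave it an adjusted p = 0.87 with an estimated correlation. Osmr, the oncostatin M receptor, rose from 0.736 to 3.84 CPM at a gene end, and a region near Il6st, encoding a receptor subunit shared by cytokines of the interleukin 6 family, fell from 1.39 to 0.384 CPM. The list's median log2 fold change was -0.0057, opposite in sign to the odds ratio. The call was lost with stratification (adjusted p = 0.18), in DESeq2 (Fisher's exact adjusted p = 0.18), in the 3 other scalings, without any single library except knockdown replicate 2 (0.12 to 0.51) and with that library alone (p = 1). With library totals 22 regions of the list were higher and 62 lower.

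Regions of genes of O-GlcNAc cycling and of the hexosamine pathway, which makes its sugar donor, were called higher more often than other regions. Of 60 regions 21 rose and 7 fell, and 26 and 9 when adjusted over the list alone (odds ratio 3.01, Fisher's exact adjusted p = 6.8e-04). Camera gave an adjusted p = 0.39 with an estimated correlation. A region within Gfpt1, the rate-limiting enzyme of the hexosamine pathway, rose from 1.19 ± 0.0870 to 6.88 ± 1.78 CPM, and one within Slc35a3, a nucleotide sugar transporter gene, from 1.02 ± 0.0592 to 4.90 ± 0.570 CPM (SD, n = 3). A region near Eogt, an extracellular O-GlcNAc transferase gene, fell from 2.80 to 1.34 CPM, a call lost without control replicate 2 (log2 fold change -0.99, edgeR adjusted p = 0.052). Oga, which removes O-GlcNAc, rose at 2 of 4 regions, from 12.1 ± 1.29 to 20.1 ± 1.94 CPM at one (chromosome 19, 45782623 to 45783023; SD, n = 3). Its most accessible region (45783465 to 45783865) had 45.5 ± 7.11 and 56.0 ± 5.93 CPM (SD, n = 3; log2 fold change 0.31, edgeR adjusted p = 0.048). That call was lost in DESeq2 (adjusted p = 0.077), with library totals (edgeR adjusted p = 0.82), reads in regions (0.098) and loess curves (0.90, log2 fold change -0.016), without control replicate 2 or 3 or knockdown replicate 1 or 3 (0.23, 0.20, 0.18 and 0.11), and with knockdown replicate 2 alone (0.53, log2 fold change 0.15). With library totals 13 regions of the list were higher and 13 lower, and its median log2 fold change moved from 0.26 to 0.0031. The median of all regions moved too, to -0.27, and the list's higher regions stayed enriched (odds ratio 3.97, Fisher's exact adjusted p = 4.7e-04).

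Regions of astrocyte, GABAergic and oligodendrocyte markers were called higher more often than other regions by Fisher's exact test. Of 104 astrocyte regions 41 rose and 6 fell, and 43 and 7 when adjusted over the list alone (odds ratio 3.64, Fisher's exact adjusted p = 2.3e-08). Camera gave the list an adjusted p = 0.51 with an estimated correlation. Its higher regions included Gfap and a region near Sox9, a glial transcription factor (0.394 to 2.28 CPM). Regions 9872 bp from Slc1a3 and 37285 bp from Aqp4, both listed markers, fell from 4.19 to 1.47 CPM and from 6.13 to 3.05 CPM. The regions inside Aqp4 went the other way and were called higher, at log2 fold changes of 1.64 to 2.10 (edgeR adjusted p under 0.05). The Gfap gene-end region had 10.9, 2.85 and 12.7 CPM in knockdown replicates 1 to 3. Of 126 GABAergic regions 38 rose and 6 fell, and 41 and 6 when adjusted over the list alone (odds ratio 2.42, Fisher's exact adjusted p = 8.8e-05; camera adjusted p = 0.87 with an estimated correlation). Regions near Pvalb, a calcium buffer gene, and Sox14, a transcription factor of midbrain inhibitory neurons, rose from 0.393 to 1.78 CPM and from 0.769 to 2.85 CPM. A second region near Pvalb and one near Lhx1, also a transcription factor gene, fell from 3.02 to 1.27 CPM and from 2.98 to 0.979 CPM. Of 105 oligodendrocyte lineage regions 30 rose and 15 fell, and 31 and 18 when adjusted over the list alone (odds ratio 2.24, Fisher's exact adjusted p = 0.0016), with a camera adjusted p = 0.87 with an estimated correlation. The myelin genes Mobp (0.382 ± 0.149 to 3.94 ± 4.69 CPM) and Mag (0.465 ± 0.172 to 3.61 ± 5.44 CPM) were called higher at gene ends, and a region within Mbp, also a myelin gene, fell from 1.901 to 0.626 CPM. The Mag call rests on knockdown replicate 1, without which the log2 fold change went from 2.92 to 0.074 (edgeR adjusted p = 0.95), and it was lost in DESeq2 (adjusted p = 0.14) and without control replicate 1 or 2 (edgeR adjusted p = 0.057 and 0.065). The Mobp gain was also smaller without that library, but stayed called.

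Summed over the list, astrocyte regions had 397 ± 18.4 CPM in control and 520 ± 86.9 CPM in knockdown (SD, n = 3; exact permutation p = 0.1, adjusted 0.18), with 576, 420 and 565 CPM in knockdown replicates 1 to 3. With knockdown replicate 2 alone 6 astrocyte and 2 oligodendrocyte regions were higher, without enrichment (Fisher's exact adjusted p = 1 and 0.22). The oligodendrocyte call was also lost in DESeq2 (adjusted p = 0.75) and without control replicate 1, 2 or 3 or knockdown replicate 1 (0.11, 0.052, 0.076 and 0.83), and the GABAergic one without control replicate 1 (0.11). With library totals the median log2 fold changes were 0.12 for astrocyte, -0.013 for GABAergic and -0.21 for oligodendrocyte regions, against 0.38, 0.25 and 0.065 with TMM. Higher and lower regions then numbered 27 and 14, 17 and 18, and 16 and 25. Higher regions of these lists stayed enriched there (odds ratios 4.98, 2.24 and 2.58, Fisher's exact adjusted p = 7.0e-09, 0.013 and 0.0042).

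Microglial regions numbered 1 higher and 3 lower of 30, the same when adjusted over the list alone, and C1qc, a complement gene, fell from 14.2 ± 1.38 to 3.84 ± 0.784 CPM (SD, n = 3). Vascular regions numbered 6 higher and 12 lower of 79, and 6 and 11 when adjusted over the list alone. Glutamatergic regions numbered 11 higher and 10 lower of 81, and 10 and 10 when adjusted over the list alone. None of these 3 lists passed Fisher's exact test (adjusted p of 0.12 or more). Summed microglial regions had 112 ± 5.64 CPM in control and 84.4 ± 3.55 CPM in knockdown (SD, n = 3), with an exact permutation p = 0.1. Camera with a preset correlation called the microglial list lower (adjusted p = 0.018). With estimated correlations camera gave the microglial, vascular and glutamatergic lists adjusted p = 0.39, 0.66 and 0.87. With library totals the lower regions numbered 11, 32 and 24, and the vascular ones were enriched (odds ratio 2.00, Fisher's exact adjusted p = 0.011).

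**Figure D3:**
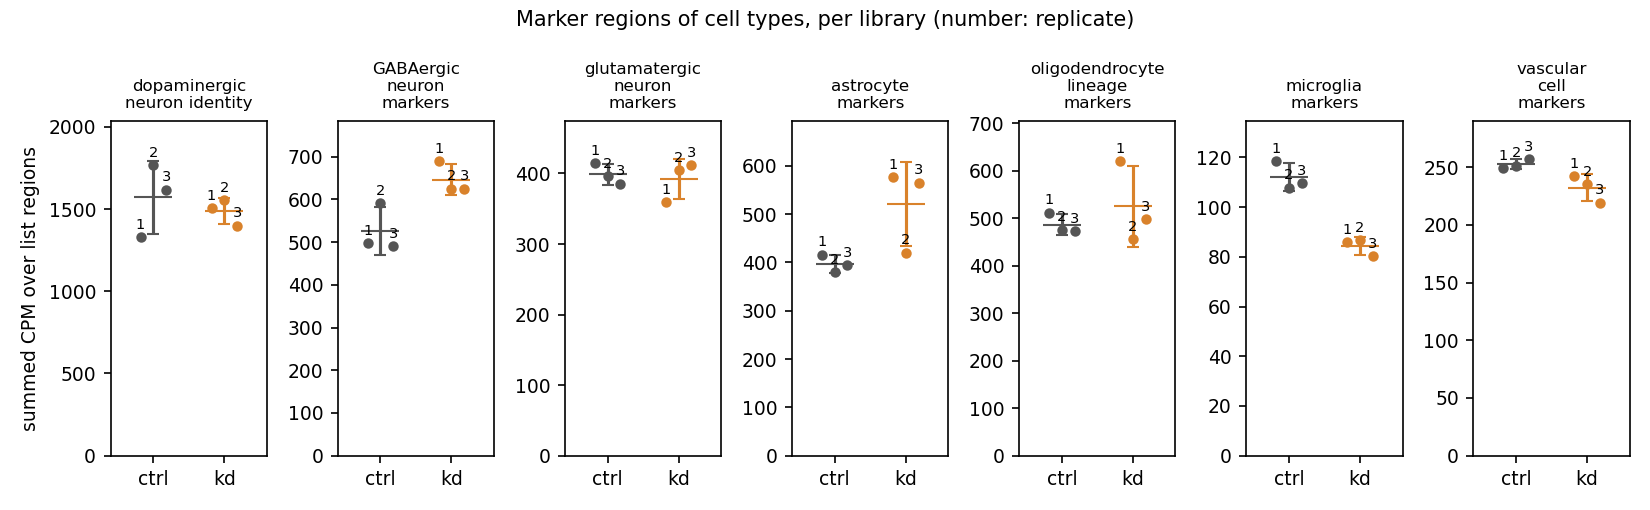
Summed CPM over the regions of each cell type list (vertical axes, from 0) in control and knockdown libraries (horizontal axes); points are libraries numbered by replicate, bars the mean and SD of 3. Astrocyte regions had 576, 420 and 565 CPM in knockdown replicates 1 to 3 against 397 ± 18.4 in control. Dopaminergic sums include the Th regions, whose gene-end region alone had 178, 379 and 245 CPM in control replicates 1 to 3. It had 237, 182 and 172 CPM in knockdown replicates 1 to 3, so that panel leans on Th.

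Regions of synaptic and channel genes were called higher less often than other regions by Fisher's exact test. Of 1332 regions of voltage-gated and pacemaker channels 135 rose and 244 fell, and 135 and 247 when adjusted over the list alone. Lower regions were enriched there (18.3% against 13.1%, odds ratio 1.49, Fisher's exact adjusted p = 6.9e-07). Camera gave an adjusted p = 0.51 with an estimated correlation. With library totals 44 were higher and 471 lower, and lower regions stayed enriched (odds ratio 1.61, Fisher's exact adjusted p = 3.1e-14). Regions within Kcnj3, a G protein-gated potassium channel gene, and Kcnma1, a calcium-activated potassium channel gene, fell from 2.38 to 0.360 CPM and from 1.17 to 0.253 CPM. A region near Kcnn3, a small-conductance potassium channel gene, rose from 0.710 to 2.57 CPM.

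Of 1673 GABA and glutamate receptor regions 152 rose and 231 fell, and 138 and 212 when adjusted over the list alone. Of 385 regions of reward-related receptors 33 rose and 55 fell, and 31 and 51 when adjusted over the list alone. Presynaptic genes had 145 higher and 153 lower of 1390, and 125 and 131 when adjusted over the list alone, and postsynaptic genes 121 and 137 of 1170, and 107 and 117. The higher shares of these lists, 9.09%, 8.57%, 10.4% and 10.3%, were below the 15.2% of all assigned regions (Fisher's exact adjusted p of 6.7e-04 or less). With estimated correlations camera gave these 4 lists adjusted p = 0.81 or more. With library totals higher and lower regions numbered 44 and 460 (GABA and glutamate receptors), 10 and 103 (reward), 61 and 327 (presynaptic) and 45 and 279 (postsynaptic). Lower regions of the GABA and glutamate receptors were enriched without knockdown replicate 3 (Fisher's exact adjusted p = 0.0136). A region within Shank2, a postsynaptic scaffold gene, rose from 1.597 to 9.26 CPM, and one near Chrna4, a nicotinic receptor subunit gene, from 1.31 to 8.01 CPM. Regions within Sv2b, a synaptic vesicle gene, and near Drd1, the D1 dopamine receptor, fell from 8.07 to 1.89 CPM and from 1.82 to 0.540 CPM. The postsynaptic shortage did not pass after stratification (adjusted p = 0.068), and with knockdown replicate 2 alone neither it (Fisher's exact adjusted p = 0.36) nor those of the reward-related receptors (0.22), the channels (0.16) and the presynaptic genes (0.061) passed.

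**Figure D4:**
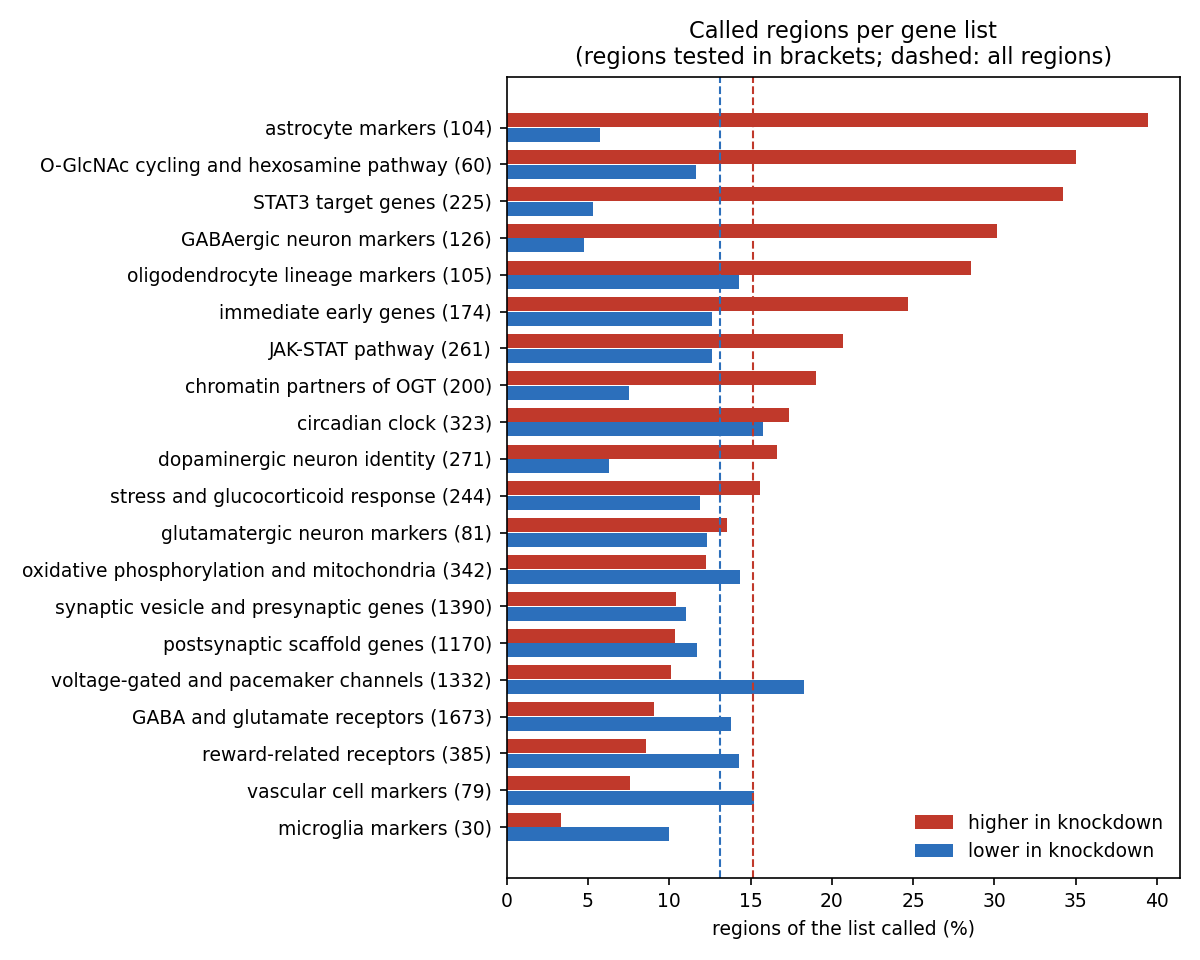
Percentage of each list's regions called higher (red) or lower (blue) in knockdown (horizontal axis) for the 20 gene lists (vertical axis, number of regions in brackets), from edgeR with TMM scaling. Dashed lines give all assigned regions, 15.2% higher and 13.1% lower; astrocyte regions were higher in 39.4% and channel regions lower in 18.3%.

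Immediate early genes, which respond to neuronal activity, had 43 of 174 regions higher and 22 lower, and 48 and 23 when adjusted over the list alone (odds ratio 1.84, Fisher's exact adjusted p = 0.0027). Camera gave an adjusted p = 0.87 with an estimated correlation. A region near Nr4a1 rose from 1.30 to 7.65 CPM, and one within Egr2 fell from 15.6 ± 1.71 to 4.06 ± 0.870 CPM (SD, n = 3). The call was lost with stratification (adjusted p = 0.18) and in DESeq2 (Fisher's exact adjusted p = 0.053). It was also lost in the 3 other scalings (0.056 to 0.45), without control replicate 2 (0.67), without knockdown replicate 3 (0.35) and with knockdown replicate 2 alone (0.38). With library totals 16 regions were higher and 33 lower.

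Chromatin partners of OGT had 38 of 200 regions higher and 15 lower, and 38 and 14 when adjusted over the list alone, with fewer losses than elsewhere (7.5%, Fisher's exact adjusted p = 0.037). Camera gave an adjusted p = 0.87 with an estimated correlation. A region near Ep300, a histone acetyltransferase gene, fell from 13.9 ± 0.467 to 4.03 ± 0.328 CPM (SD, n = 3). The shortage was lost after stratification (adjusted p = 0.10), without control replicate 3 (0.080), without knockdown replicate 3 (0.064) and with knockdown replicate 2 alone (0.086). It was also lost with assignment within 10000 bp (0.10), reads in regions (0.059) and loess curves (0.054). With library totals 12 regions were higher and 34 lower, and with reads in regions 25 and 24. The shortage of losses stayed with library totals (odds ratio 0.60, Fisher's exact adjusted p = 0.013).

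The stress and glucocorticoid list had 38 regions higher and 29 lower of 244, the same when adjusted over the list alone. The mitochondrial list had 42 and 49 of 342, and 42 and 48 when adjusted over the list alone, and the circadian clock list 56 and 51 of 323, and 58 and 57. None of these differed from other regions by Fisher's exact test (adjusted p of 0.26 or more), though circadian regions were enriched among higher ones without knockdown replicate 2 (Fisher's exact adjusted p = 0.043). With library totals higher and lower regions numbered 9 and 57 (stress), 17 and 89 (mitochondrial) and 22 and 85 (circadian). Of all 191732 regions 47194 were lower in that scaling. Lower regions of these lists were not enriched there (odds ratios 0.89, 1.03 and 1.05, Fisher's exact adjusted p = 0.64, 0.87 and 0.80). Single regions passed, such as one within Nr1d2, a clock repressor gene, which rose from 1.124 to 5.41 CPM, and one within Rorb, a nuclear receptor gene, which fell from 3.24 to 0.481 CPM. Over the 20 lists, Fisher's exact test found higher regions enriched in 7 and scarcer in 5, and lower regions enriched in 1 and scarcer in 5. Camera gave 6 lists with a preset correlation and 0 with an estimated one (1 at an unadjusted p under 0.05).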

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

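The 3 scalings other than TMM, stratification, camera and knockdown replicate 2 alone were chosen after the results were seen; the other settings were planned. The cause of these changes was not tested. Leaving out 1 library in turn gave 19120 to 29915 higher and 14668 to 25053 lower regions. Gene-end regions were then 20.9% to 33.4% higher and 3.97% to 6.83% lower, 4 to 8 lists were enriched among higher and 1 to 2 among lower regions, and Slc18a2 had log2 fold changes of -0.062 to 0.30. DESeq2 gave 14862 lower regions and 4 lists among higher ones. With grouping by title edgeR gave 0 higher and 0 lower regions, hence 0% of gene-end regions and 0 lists in either direction, with 23390 regions at an unadjusted p under 0.05. Log2 fold changes turned there to -1.05 (Gm9733), 0.083 (Nr4a2), -0.996 (Mobp), -2.41 (Mag) and -0.13 (Fos). Library totals gave 13072 higher and 47194 lower regions, 8.72% and 15.5% of gene-end regions, 2 lists among lower regions, and values of -0.10 for Slc6a3 and -0.092 for Slc18a2. Reads in regions gave 10.8% of gene-end regions lower. Loess curves gave 18.6% of gene-end regions higher and 11.5% lower, and -0.016 for Oga. Knockdown replicate 2 alone, assumed to vary like the controls, gave 11339 higher and 10790 lower regions, 12.7% and 3.82% of gene-end regions and 2 lists among higher regions. Log2 odds ratios were then -0.037 (astrocyte), -1.66 (oligodendrocyte) and -0.12 (JAK-STAT), and log2 fold changes 0.15 (Nr4a2) and -1.54 (Mag). Calls ended there at regions of Sox9, Otx2, Osmr, Il6st, Pvalb, Nr4a1, Drd1, Kcnma1 and Tigar. List assignment within 10000 bp gave 2 lists among lower regions. Camera gave 4 and 2 lists with a preset correlation, and 0 and 0 with an estimated one. Of the alternative values for named regions 1404 kept direction and side of the threshold, 215 kept direction but no longer passed and 5 newly passed. Of those for list odds ratios 179 kept both and 52 direction alone. In none of these settings was a region called in the direction opposite to its main call. With grouping by title no odds ratio could be formed. Alternatives written for peak lists (thresholds, list lengths, overlap, windows, contigs and motif settings) were not run, because the tables hold counts. No paired analysis was possible because the groups share no replicate numbers in the labels' titles. Depth limits low regions, where 3 reads equal 0.117 to 0.237 CPM.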

Other observations

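The tests in this part, other than the count over splits, were chosen after the results were seen. A list of 31 p53 target genes was written after Cdkn1a and Mdm4 had been seen among strong gains, and it was 1 of 21 gene groups viewed then. Of its 192 regions 77 were higher and 15 lower in knockdown (odds ratio 3.75). Of the 31 genes 26 had a higher region and 11 a lower one. This gene count says little, since 15 of 16 circadian clock genes and 31 of 36 GABA and glutamate receptor genes had a higher region. Mdm4, a p53 inhibitor gene, rose inside the gene (mm10 chromosome 1, 133019359 to 133019759) from 0.782 ± 0.190 to 10.5 ± 1.55 CPM (SD, n = 3). Cdkn1a, encoding the cell cycle inhibitor p21, rose at a gene end (chromosome 17, 29090738 to 29091138) from 1.03 ± 0.182 to 9.96 ± 1.23 CPM (SD, n = 3). Bax, Bbc3 and Zmat3, p53 targets of apoptosis or growth arrest, rose at log2 fold changes of 2.20, 2.22 and 2.35. A second Mdm4 region fell (-1.05), as did one within Tigar (-1.04). With library totals 48 of the 192 regions were higher and 30 lower, and the list's median log2 fold change was 0.045, against 0.30 with TMM. The odds ratio for higher regions was 4.80 there.

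Of 20 gene families viewed in the same step, taken by gene name over regions within 10000 bp, proteasome genes had 53 of 169 regions higher and 5 lower (odds ratio 2.52, Fisher's exact adjusted p = 1.6e-06). Zinc finger genes had 370 of 1841 higher and 210 lower (odds ratio 1.39, adjusted p = 8.6e-07). Regions of Sox, Nduf, ribosomal protein and heat shock genes were also called higher more often than other regions (odds ratios 1.95, 1.82, 1.65 and 1.58). Regions of collagen and potassium channel genes were called higher less often (odds ratios 0.499 and 0.681). These families were tested with TMM scaling alone, over regions that are not independent, and without stratification by location.

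The number of called regions was compared over the 10 splits of the 6 libraries into equal groups. The real split gave 53819 calls, the highest of the others 0, so 1 split reached the real value. With 10 splits no share under 0.05 can be had.

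For the p53 pattern, a stratified odds ratio of 3.14 (95% interval 2.32 to 4.27) argued against location and accessibility as its whole cause. It covers all 31 genes, with the Cdkn1a and Mdm4 gains that prompted the list. Among the 29 genes not seen before the list was written 38.9% of regions were higher, against a median of 20.2% and a highest value of 34.5% in 10000 random lists (share 0.0001, the smallest they can give). Replicate 2 was the lowest knockdown library at 64.9% of higher p53 regions against 50.4% of other higher regions (Fisher's exact p = 0.0118). Astrocyte nuclei in knockdown replicates 1 and 3 would give such a share. The astrocyte and oligodendrocyte lists had the highest of these shares (85.4% and 83.3%). A raised share is not particular to glial lists, since circadian clock regions had 71.4% and JAK-STAT regions 68.5%. Dopaminergic, GABAergic and glutamatergic regions had 46.7%, 28.9% and 18.2%, and mitochondrial regions 21.4%. Whether astrocyte nuclei contribute therefore stays open. With replicate 2 alone, however, 49 of 193 p53 regions were higher (odds ratio 5.61). An effect of the genotype remains a hypothesis, beside nuclei of other types and effects of Cre or virus; camera gave the list p = 0.023 with an estimated correlation, not adjusted for the 21 groups.

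For the astrocyte pattern, a lower share of dopaminergic nuclei was predicted to raise microglial and vascular regions as well. They had a median log2 fold change of -0.21 (95% interval -0.35 to -0.094) and astrocyte regions 0.38 (0.22 to 0.84). This cannot decide the question, because nuclei were sorted for fluorescence and the other nuclei kept need not include microglial or vascular ones. With TMM, GABAergic and oligodendrocyte regions went the way such a share would give, with 38 and 30 higher against 6 and 15 lower. With library totals 17 and 16 were higher against 18 and 25 lower, though higher regions stayed enriched (odds ratios 2.24 and 2.58). The oligodendrocyte enrichment was lost in DESeq2 (Fisher's exact adjusted p = 0.75). Regions of the dopaminergic identity list went the other way with TMM, with 45 higher and 17 lower. Their lower regions stayed scarcer than elsewhere with library totals (odds ratio 0.51). With TMM that shortage did not pass without control replicate 1 or without knockdown replicate 2. Glutamatergic regions had 11 higher and 10 lower. Regions up to 100000 bp from dopaminergic genes need not be open in such nuclei alone. With values on both sides, a lower share of dopaminergic nuclei stays open. Replicate 2 was the lowest knockdown library at 85.4% of the 41 higher astrocyte regions, against 50.4% of other higher regions; this raised the question of astrocyte nuclei in replicates 1 and 3 and is no test of it, so that explanation stays open. A region 1170 bp from Gfap had 16.3, 3.403 and 16.7 CPM in knockdown replicates 1 to 3 and 1.41 ± 0.339 CPM in control (SD, n = 3). The sort for Cre-dependent fluorescence would remove cells that do not express Cre, 1 of the 10 astrocyte genes is also in the STAT3 target list, and a change of chromatin with the genotype, in either cell type, stays open.

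For Th, the 3 regions at and beyond the gene end differed between control libraries by a log2 range of at least 1.09, against 0.28 for the region inside the gene. Regions of the other dopaminergic identity genes had a median log2 ratio of control replicate 2 to replicate 1 of 0.039 (95% interval -0.020 to 0.079), against 1.26 at the Th regions. This cannot exclude a differing share of dopaminergic nuclei, because regions up to 100000 bp from these genes need not be open in such nuclei alone. Main regions were mixed, with 7.22 and 11.2 CPM in control replicates 1 and 2 at Drd2 and 4.03 and 5.15 CPM at Slc18a2. Slc6a3 had 4.03 and 3.83 CPM, Nr4a2 22.6 and 21.9 CPM, and Pitx3 16.9 and 17.1 CPM. The least variable of the 3 Th regions lay at percentile 99.7 of 1172 regions of 50 CPM or more, which describes the unevenness and tests no source of it. Reads from a Th promoter in the injected vector, whose sequence was not used here, stay open as a source, untested. The control libraries share 1 genotype, so no explanation by the study's groups could be tested.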
